A study of Mus musculus with 6 samples.

How the data were processed

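Poly-A RNA of heart muscle cells isolated from mice by perfusion was sequenced as paired ends from libraries of a kit that marks strand, per the labels' protocols. The submitters' processing notes name FastQC, TopHat2, SAMtools, HTSeq and DESeq2 without versions, and the mm10 build. The deposited values are counts of reads per gene made by the authors, whole numbers with no normalization, for 46078 gene identifiers in each of 6 libraries. The strand setting of the counting is not given in the sources used here. The deposited tables also hold rows that name no gene, which stayed out of library sizes and tests. These rows took 97.4% to 97.7% of all entries of a library, mostly reads in no feature.

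Libraries were grouped by their titles as Acly_KD (n = 3) and control (n = 3). The chi-square per degree of freedom between libraries of one group was 4.37 to 13.4, so no library was a repeat of another in its group. Features were matched by identifier to the GENCODE M21 annotation of the same build, which held 45143 of the 46078. For each feature the exonic bases shared with exons of genes on the other strand were counted.

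Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr with a minimum count of 10, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. This design was fixed before the data were examined and assumed counts of mRNA. After the strand of the counts had been seen, a second reading was added. A nuclear feature's counts were given to the gene with at least 80% of its opposite-strand overlap and at least 50 shared bases, if that gene's own count was lower or the gene was absent from the count tables. Counts were summed per gene and tested in the same way. In all, 3 forms of this rule were run. The form reported was the first; a second, limited to genes that are also in the count tables, was used for a time as the main one and returned to an alternative, since it was chosen with the calls of the first in view and moved 1 gene list past the threshold. The last form asked for 200 bases shared with a single gene.

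Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, where 3 or more members were tested, out of 48 lists fixed before the data were examined. Genes were named by a rule also fixed then: Acly; up to 12 genes in each direction with the largest change among those passing the test, with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a predicted gene or clone; where fewer than 5 passed in a direction, the 5 with the smallest p; and up to 4 passing members of each list, or otherwise the 2 most abundant. Gm46367, Irs1, Irs2, Uchl1, Ace and Slc33a1 fall outside that rule and were chosen after their values were seen, as were the lists whose abundant members are printed, and for the reading of mRNA the rule was applied a second time. CPM values are normalized by TMM within the features tested, and fold changes are Acly_KD over control. Intervals at 95% use the standard error taken from the fold change and the test statistic, and the t distribution with the degrees of freedom of the test. A count of 0 was given a floor of 3 counts.

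The steps were tested on simulated counts with 200 changed genes. As deposited, with 2952 features, the test recovered 4.48% of the 1.5-fold, 19.4% of the 2-fold and 54.5% of the 3-fold changes. In the reading of mRNA, with 1453 genes, it recovered 28.4%, 44.8% and 86.4%, and 5.36% of its calls were genes that had not been changed. Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals, limma-voom with quality weights, 2 other filters, a replicate block, mitochondrial genes left out, other list tests, and each library left out. Added after the data were seen were all uniquely aligned reads as library size, a term for the libraries with reads opposite to Xist, a term for the ratio of wrong-strand to mRNA reads, features with or without opposite-strand exons alone, and Acly_KD replicates 1 and 2 left out, which sets 1 Acly_KD library against 3 controls.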

Results

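RNA from isolated mouse heart muscle cells was sequenced in 2 groups, cells with a knockdown of Acly (Acly_KD, n = 3) and wildtype cells (control, n = 3), which asks how the transcripts of these cells differ when Acly is reduced. Acly encodes ATP citrate lyase, the enzyme that makes cytosolic acetyl-CoA from citrate. The deposited values were read counts for 46078 gene features in each of the 6 libraries. Reads counted in features numbered 672133, 460222 and 799868 in Acly_KD replicates 1 to 3 and 271463, 814765 and 753509 in control replicates 1 to 3. These were 2.81% to 3.07% of the uniquely aligned reads of each library, and 96.7% to 96.9% fell in no feature. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

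The counts had the pattern of reads assigned to the strand opposite to the transcript. Of the 45106 nuclear features matched to the annotation, 18.0% had exons that overlapped an exon of another gene on the other strand, and these held 91.9% of the nuclear counts. Among the 100 nuclear features with the most counts, 97 had such an overlap. mt-Nd6, the mitochondrial protein gene annotated on the other strand from the remaining 12, took 82.6% of the mitochondrial counts. The library kit marks strand, and the strand setting of the counting is not given in the sources used here. Each feature was therefore read in 2 ways, first as deposited, and then as a reading of mRNA, in which the counts of a feature were given to the gene whose exons lie opposite to it. The second way was chosen after the counts had been seen. It gave 2973 genes, with 140295 to 445228 reads per library.

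Acly itself (chromosome 11, 100476353 to 100528000, mm10) received 0, 0 and 0 reads in Acly_KD replicates 1 to 3 and 1, 5 and 6 reads in control replicates 1 to 3. The Acly_KD group was given a floor of 3 counts, and the 12 control reads were taken as exact. On that basis Acly was at least 4.20-fold lower in Acly_KD, a log2 change of -2.07 or below. Each Acly_KD library separately allowed up to 3.75 to 6.52 CPM (reads scaled to library size) at 0 reads, which is above the 3.68 CPM of control 1. A two-sided exact permutation test of the CPM values gave p = 0.1, the smallest that 3 libraries against 3 allow. No exon of another gene lies opposite to Acly, so these are reads of the wrong strand at its own locus and a limited check of its mRNA. Wrong-strand reads per mRNA read were lower in Acly_KD replicates 1 and 2 than in the controls, as described below. This check does not separate that difference from lower Acly mRNA. Floors cover counting error only. The bound without Acly_KD replicate 3 was -1.30 and without Acly_KD replicate 1 it was -1.45. Scaled to reads of features with no opposite-strand exons, the bound with all libraries was -1.81.

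In the reading of mRNA, 3 genes were higher and 3 were lower in Acly_KD among 1453 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Ccnd1, which encodes cyclin D1, a regulator of entry into the cell cycle, rose from 388 ± 50.1 CPM in control to 671 ± 94.0 CPM in Acly_KD (SD, n = 3 each), a log2 fold change of 0.80 (SE 0.17, adjusted p = 0.0366 in edgeR). Mrtfb, which encodes a coactivator of serum response factor, rose from 30.7 ± 11.8 to 111 ± 61.0 CPM, with a log2 fold change of 2.00 (SE 0.44, adjusted p = 0.0422 in edgeR). The Mrtfb values rest on few reads, 63, 12 and 41 in Acly_KD replicates 1 to 3 and 6, 13 and 7 in control replicates 1 to 3. Gm46367, a predicted gene, rose by a log2 fold change of 1.02 and lay at the threshold, with an adjusted p in edgeR that rounds to 0.05. Jund, an AP-1 transcription factor gene, fell from 1179 ± 197 to 704 ± 119 CPM, with a log2 fold change of -0.76 (SE 0.15, adjusted p = 0.0366 in edgeR). Cebpb, a transcription factor gene of the C/EBP family, fell from 1026 ± 51.1 to 568 ± 187 CPM, with a log2 fold change of -0.84 (SE 0.18, adjusted p = 0.0422 in edgeR). Phkg1, the muscle catalytic subunit of glycogen phosphorylase kinase, fell from 280 ± 54.4 to 127 ± 25.0 CPM, with a log2 fold change of -1.14 (SE 0.24, adjusted p = 0.0366 in edgeR). For each of the 6 genes, all 3 Acly_KD libraries lay on one side of all 3 controls. Groups were apart in this way for 14.7% of the 1453 genes, and for 11.4% of features as deposited, where chance gives 10%.

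**Figure D1:**
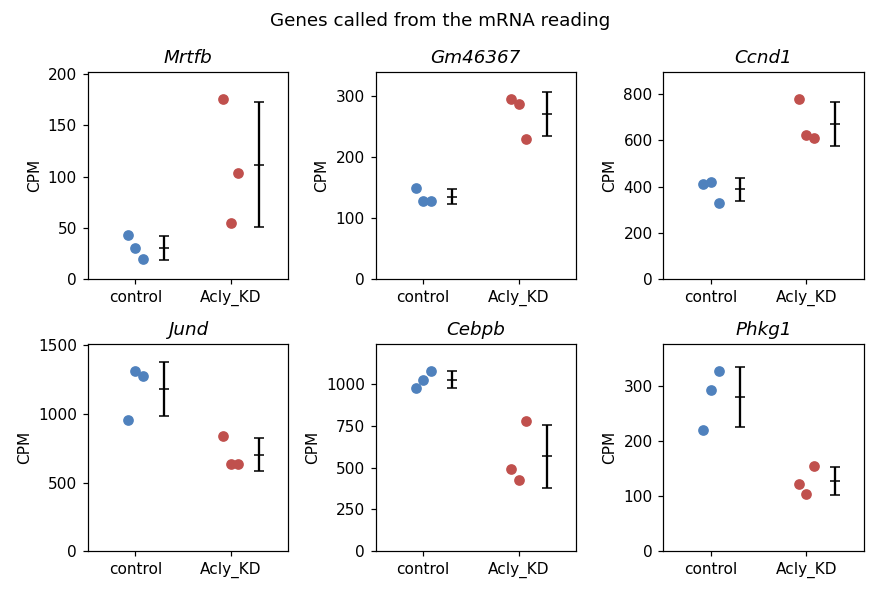
Normalized read counts (CPM, linear axes from 0) of the 6 genes called from the reading of mRNA, with 1 point per library and, beside the points, the group mean with its SD (n = 3). The Acly_KD points of Mrtfb, Gm46367 and Ccnd1 lie above all controls, and those of Jund, Cebpb and Phkg1 lie below them.

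These values are the whole counts of features that share short stretches of exon with each gene. Ccnd1 (chromosome 7, 144929931 to 144939925) was read through 1100 bases of exon shared with LTO1, and Jund (chromosome 8, 70698949 to 70700616) through 877 bases shared with Gm11175. Phkg1 (chromosome 5, 129863421 to 129898549) was read through 630 bases shared with Sumf2, and Cebpb (chromosome 2, 167688915 to 167690418) through 312 bases shared with Tmem189. Mrtfb (chromosome 16, 13256481 to 13417529) was read through 162 bases shared with Gm15738, and Gm46367 through 166 bases shared with Numb. Reads of a gene, reads counted elsewhere in its partner and reads of a transcript antisense to that partner cannot be told apart here.

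The calls changed with the libraries and settings used. The log2 fold changes kept their direction with each single library left out, which follows from groups that do not overlap. They then ran from 0.68 to 0.88 for Ccnd1, 1.53 to 2.28 for Mrtfb, 0.95 to 1.14 for Gm46367, -0.91 to -0.67 for Jund, -1.15 to -0.69 for Cebpb and -1.31 to -1.01 for Phkg1. Fewer libraries also give the test less power. Without control replicate 1, 2 or 3 the test called 0 genes higher and 3, 1 and 2 lower, of which 2, 0 and 0 were among the 6 genes above. Without Acly_KD replicate 1 or 2 it called 1 higher and 1 lower each time, with 1 of the 6 among them, and without Acly_KD replicate 3 it called 8 higher and 12 lower, with 5 of the 6. With library totals as the scale it called 4 higher and 2 lower, with DESeq2's test 1 higher and 3 lower, and with all uniquely aligned reads as library size 0 higher and 2 lower, of which 5, 4 and 2 were among the 6. A stricter filter on low counts left 0 calls in either direction by edgeR, with 81 genes at an unadjusted p under 0.05. Reads opposite to Xist, the RNA that coats the inactive X chromosome of female cells, numbered 129 and 124 in control replicates 2 and 3 and 0 in control 1 and in all 3 Acly_KD libraries. The rule of the reading of mRNA gives these reads to Xist. The Xist feature itself held few reads, 3, 0 and 2 in Acly_KD replicates 1 to 3 and 0, 2 and 4 in control replicates 1 to 3. At 4 genes of the Y chromosome (Ddx3y, Uty, Eif2s3y and Kdm5d) 1, 1 and 2 reads of the wrong strand were counted in Acly_KD replicates 1 to 3 and 2, 2 and 0 in control replicates 1 to 3, too few to give the sex of a library. With a term for control replicates 2 and 3, the libraries with reads opposite to Xist, edgeR called 0 genes, with 96 at an unadjusted p under 0.05. With a term for the ratio of wrong-strand to mRNA reads described below it called 1 higher and 2 lower, with 1 of the 6 among them.

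Genes that came next in the reading of mRNA did not pass the threshold. Above zero, the log2 fold changes were 0.58 (SE 0.14) for Ttn, which encodes titin, the giant spring protein of the sarcomere, 0.57 (SE 0.15) for Ppp1r14c and 1.82 (SE 0.47) for B3galt2, each with an adjusted p of 0.0731 in edgeR, and 0.88 (SE 0.24) for Hectd2os and 0.56 (SE 0.16) for Arhgef11, with adjusted p of 0.0905 and 0.115. Below zero, they were -1.10 (SE 0.28) for Lrrc8dos, -1.19 (SE 0.30) for Mapk1ip1, -0.35 (SE 0.09) for Txnip, an inhibitor of glucose uptake, and -0.90 (SE 0.23) for Coq10b, a mitochondrial coenzyme Q binding protein, again at an adjusted p of 0.0731 in edgeR, and -1.05 (SE 0.28) for H19 at 0.0852. Txnip was among the most abundant genes, with 29155 ± 2034 CPM in control and 22800 ± 540 CPM in Acly_KD (SD, n = 3 each).

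The gene lists fixed before the data were examined did not pass as groups in this reading: camera called 0 of 15 lists with 3 or more measured members (adjusted p under 0.05). Insulin and AMPK signalling came closest, with 5 of 6 members below zero, a median log2 fold change of -0.25 and an adjusted p of 0.0639, or an adjusted p of 1.00 with an estimated correlation. Over all genes 0 of its members passed, and adjusted over the list alone 3 passed, namely Txnip, Irs1 (-0.50, SE 0.17) and Irs2 (-1.51, SE 0.51), the last pair being the insulin receptor substrates. In the autophagy and atrophy list 1 member passed when adjusted over the list alone, with a value below zero. In the stress and fetal gene list, adjusted over the list alone, Uchl1 (-1.44, SE 0.45) and Ace (0.55, SE 0.17) passed, in opposite directions. Myh7 read 15527 ± 12090 CPM in control and 6050 ± 906 CPM in Acly_KD, with groups that did not overlap, a log2 fold change of -1.36, a 95% interval from -3.08 to 0.36 and an adjusted p of 0.621 in edgeR. Control replicate 3 held the highest value of Myh7, 29362 CPM against 6993 and 10226 CPM in control replicates 1 and 2, and without it the log2 fold change of Myh7 was -0.50 (adjusted p = 0.194 in edgeR). At its own locus its groups did not overlap either, with a log2 fold change of -0.52 (SE 0.18, adjusted p = 0.579 in edgeR). That feature shares 1149 exonic bases with genes on the other strand, Mhrt among them. Its counts can come from their transcripts and are not a separate measure of Myh7 mRNA. Nppa read 4744 ± 2988 and 7026 ± 4454 CPM, with groups that overlapped (adjusted p = 0.914 in edgeR).

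For some of the other lists abundant members are given, and none of these genes passed the test by edgeR. Acadvl, a mitochondrial fatty acid oxidation enzyme, read 32521 ± 1824 CPM in control and 32090 ± 1353 CPM in Acly_KD (SD, n = 3 each), with a 95% interval of the log2 fold change from -0.20 to 0.16. For Fabp3, the heart fatty acid binding protein, the interval was -0.29 to 0.18. In the calcium handling list it was -0.16 to 0.22 for Atp2a2, the calcium pump of the sarcoplasmic reticulum, and 0.07 to 0.71 for Asph. It was -0.07 to 0.33 for Pdha1, a subunit of pyruvate dehydrogenase, and -0.17 to 0.21 for Mpc1, a mitochondrial pyruvate carrier. For Ckm, the muscle creatine kinase, which read 51720 ± 2027 CPM in control and 45164 ± 3473 CPM in Acly_KD, it was -0.37 to -0.02. The groups did not overlap for Asph and Ckm, as for 14.7% of all genes tested, and their adjusted p in edgeR was 0.408 and 0.471. Of the list of citrate and cytosolic acetyl-CoA genes, in which Acly acts, 6 other members were measured and 0 passed, whether adjusted over all genes or over the list alone. The acetyl-CoA transporter Slc33a1 had the largest value among them, a log2 fold change of 0.75 (SE 0.28, adjusted p = 0.329 in edgeR).

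Read as deposited, 0 features were called higher and 0 lower among 2952 tested by edgeR, with 180 at an unadjusted p under 0.05 where chance gives 147.6. DESeq2's test also called 0, and limma-voom with quality weights called 1 higher and 2 lower. The 5 named features with the smallest p in each direction did not pass the adjustment. Higher values were found for LTO1, Numb, Itfg1, Cdc73 and mt-Nd5, with log2 fold changes of 0.83, 1.05, 0.97, 1.88 and 0.51, and lower values for Sumf2, Tmem189, Slc38a6, Ppp2r2d and Lrrc8d, at -1.12, -0.83, -0.61, -1.18 and -1.07, all with adjusted p from 0.447 to 0.457 in edgeR. LTO1, Numb, Sumf2 and Tmem189 are the features through which Ccnd1, Gm46367, Phkg1 and Cebpb were read. Without Acly_KD replicate 3 the test called 23 features higher and 46 lower, without Acly_KD replicate 1 it called 1 higher, and without control replicate 1 it called 2 lower.

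Of 31 lists with 3 or more members tested as deposited, camera called 11, of which 10 were lower and 1 higher in Acly_KD. All 22 sarcomere genes measured had values below zero, with a median log2 fold change of -0.38 and an adjusted p of 9.16e-05, and so did 30 of 36 nuclear genes of the respiratory chain (median -0.39, adjusted p = 0.000857). Calcium handling (10 of 10 genes below zero), glycolysis and lactate (16 of 17), pyruvate dehydrogenase and the TCA cycle (14 of 19) and fatty acid uptake and beta-oxidation (14 of 17) were also called lower, as were the lists for lipid droplets (6 of 6), mitochondrial biogenesis (9 of 10), stress and fetal genes (7 of 10) and ketone bodies (4 of 4). The list of mitochondrially encoded proteins was called higher, with 8 of 10 genes above zero and a median of 0.38; its medians were 0.11, 0.47 and 0.62 in Acly_KD replicates 1 to 3 and from -0.11 to 0.12 in the controls. With an estimated correlation 0 of the 11 calls held, each with an adjusted p of 0.663. Over all genes 0 members of any of these lists passed. Adjusted over the list alone, 1 member passed among the mitochondrially encoded proteins and 1 among the stress and fetal genes.

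The lower lists were not equally low in the 3 Acly_KD libraries. The median sarcomere gene lay at -1.59 and -0.57 (log2, against the control mean) in Acly_KD replicates 1 and 2 and at 0.32 in replicate 3, where the controls spanned -0.27 to 0.14. In 9 of the 10 lists Acly_KD replicate 3 had the highest median of its group. The other was the stress and fetal list, at -0.84, -0.23 and -0.34 in Acly_KD replicates 1 to 3 and from -0.22 to 0.06 in the controls. Reads on the wrong strand at a gene's own locus were compared with the mRNA reads of the same gene for 119 genes. This ratio, relative to the mean of the 6 libraries, had a median of 0.569 and 0.917 in Acly_KD replicates 1 and 2, 1.40 in Acly_KD replicate 3, and 1.30, 1.22 and 1.06 in the controls. With a term for this ratio, an alternative added after the data were seen, camera called 1 list as deposited and the sarcomere median was -0.03. The 119 genes included members of the lower lists, such as Ttn, Atp2a2 and Gpi1, so the term is not independent of these lists.

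**Figure D2:**
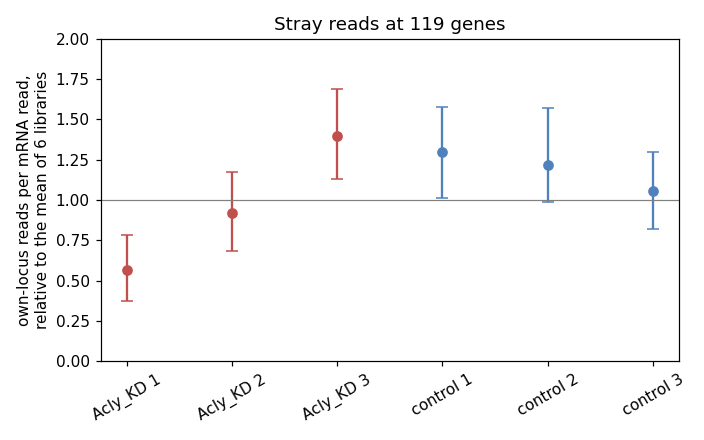
Reads on the wrong strand at a gene's own locus per mRNA read of the same gene, relative to the mean of the 6 libraries (linear axis), as the median (point) and quartiles (bars) over 119 genes. The medians of Acly_KD 1 (0.569) and Acly_KD 2 (0.917) lie below the lowest control (1.06), and that of Acly_KD 3 (1.40) lies above the highest (1.30).

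The members of the 10 lower lists did not show the same shift in the reading of mRNA. Their median log2 fold change was -0.43 over 150 genes at their own loci and 0.03 over the 33 genes read as mRNA. For the latter the bootstrap 95% interval, taken over genes and not over libraries, was -0.02 to 0.13. For the 19 genes with both, 15 had the lower value at their own locus, and the medians were -0.45 and 0.02. The lists were picked for low values at their own loci in these data. Values nearer to zero in another reading can follow in part from that choice.

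**Figure D3:**
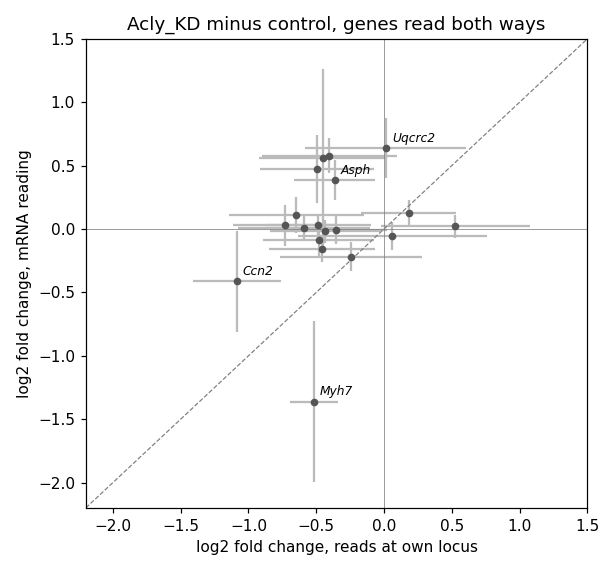
Log2 fold changes (Acly_KD minus control) of the 19 genes of the lower lists that were measured at their own locus (horizontal axis) and as mRNA (vertical axis), with standard errors, and the line of equal values dashed. Of the 19 points, 15 lie above the dashed line. The lists were picked for low own-locus values in these data, which favours that side.

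Markers of other cell types were measured in both readings. As deposited, the lists for atrial muscle cells (3 genes, median -0.45), endothelial cells (3 genes, median -0.14) and pericytes and smooth muscle (4 genes, median -0.01) were not called, with camera adjusted p of 0.337, 0.526 and 0.862. The endothelial genes varied between libraries, with medians of -1.73, -1.01 and 0.90 (log2, against the control mean) in Acly_KD replicates 1 to 3 and from -0.56 to 0.27 in the controls, and were lowest in the libraries in which the sarcomere genes were lowest. In the reading of mRNA too few markers were measured for a test of these lists. Of the atrial markers, Kcnj3 read 1434 ± 148 CPM in control and 1091 ± 48.2 CPM in Acly_KD, with groups that did not overlap and a log2 fold change of -0.40 (SE 0.13, adjusted p = 0.230 in edgeR), while the value for Nppa, given above, lay above zero. The log2 fold changes were -0.40 (SE 0.34) for Eng, an endothelial marker, and 0.21 (SE 0.23) for Notch3, a marker of pericytes and smooth muscle, with adjusted p of 0.788 and 0.872 in edgeR.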

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

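The alternatives for the reading of mRNA, the terms for reads opposite to Xist and for the ratio of wrong-strand reads, the features with or without opposite-strand exons alone, the libraries left out together and the scale of uniquely aligned reads were chosen after the data were seen; the others were planned. Without Acly_KD replicates 1 and 2, Acly_KD replicate 3 stands alone and is assumed to vary like the controls, so its values are those of 1 library. As deposited, 0 features were called in either direction, also with DESeq2's size factors or test, library totals, the stricter filter, the replicate block and mitochondrial genes left out. limma-voom with quality weights called 1 higher and 2 lower, no filter 2 and 1, the term for the ratio 4 and 1, and the fit without Acly_KD replicates 1 and 2 called 10 and 26. With single libraries left out the counts ran from 0 to 23 higher and from 0 to 46 lower. All uniquely aligned reads as library size moved the median log2 fold change of all features from -0.04 to -0.14. The Acly bound of -2.07 ran from -2.18 to -1.30 with single libraries left out; the unfiltered edgeR fit gave -4.99 (adjusted p = 0.736), which depends on the prior count.

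From the reading of mRNA (3 higher, 3 lower), DESeq2's test called 1 higher, limma-voom 7 higher and 7 lower, no filter 12 and 18, and the stricter filter 0 and 0. Uniquely aligned reads as library size gave 0 higher, the term for reads opposite to Xist 0 and 0, and the term for the ratio 1 and 2. The overlap of 200 bases gave 1 higher and 3 lower, and 4 of these were among the 6 genes. Mrtfb and Gm46367, read through 162 and 166 bases, could not enter that form. limma-voom and no filter each kept all 6 genes. With single libraries left out the counts ran from 0 to 8 higher and from 1 to 12 lower. The replicate block gave 5 higher and 7 lower, and 1 called list instead of 0. Libraries with the same number did not deviate together (r = -0.07, -0.02 and -0.18 as deposited), so the numbers were not taken as pairs; the block left the 0 calls and 11 lists as deposited. The list called under the block was insulin and AMPK signalling (adjusted p = 0.0213), which was also the 1 list called when only genes in the count tables were read (adjusted p = 0.0473), against 0.0639 in the reported form. Single libraries left out gave 0 to 1 called lists.

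The 11 lists called as deposited fell to 3 with the stricter filter, 5 with the term for reads opposite to Xist, 1 with the term for the ratio, 4 without Acly_KD replicates 1 and 2, and 0 with features that have opposite-strand exons alone, with those that lack them alone, with an estimated correlation and with fry in its directional and its mixed form. With single libraries left out 2 to 16 lists were called. Without Acly_KD replicates 1 and 2 the sarcomere list was called higher (median 0.32, adjusted p = 0.00506), and the median lay above zero, with adjusted p from 0.0517 to 0.394, for the respiratory chain (0.21), calcium handling (0.24), glycolysis (0.18), lipid droplets (0.16), pyruvate dehydrogenase and TCA cycle (0.41) and beta-oxidation (0.26). camera's direction turned while the median stayed below zero for mitochondrial biogenesis without those libraries (-0.0027, adjusted p = 0.608), for glycolysis with the stricter filter (-0.12, adjusted p = 0.738) and for beta-oxidation with the term for the ratio (-0.12, adjusted p = 0.851). Fewer features tested or fewer libraries account for part of these shifts by construction, and otherwise the cause was not tested. What depth limits was not tested; as deposited 19.4% of simulated 2-fold changes were recovered, and in the reading of mRNA 44.8%.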

Other observations

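The tests of the mRNA of the lower lists and of the strand itself were chosen after the results were seen; the tests of the ratio of wrong-strand reads, of the term for it, of reads opposite to Xist and of the splits were written before theirs, that of the term after earlier tests of wrong-strand reads had been seen. The test of reads opposite to Xist was made stricter after its result was seen, by asking for a margin of 1 standard error, which moved that explanation from excluded to open, and the earlier tests of wrong-strand reads in the 6 genes were dropped because one rested on 1 library and the others on intervals that the calls themselves had set.

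Libraries also differed in single abundant transcripts. Reads opposite to Gm42418, a gene that overlaps ribosomal RNA sequence, came to 676, 193 and 251 CPM, here scaled to all uniquely aligned reads, in Acly_KD replicates 1 to 3 and 238, 627 and 514 in control replicates 1 to 3. Reads under Mhrt, which lies opposite to Myh7, were 100, 70.0 and 97.6 CPM on the same scale in Acly_KD replicates 1 to 3 and 108, 164 and 439 in control replicates 1 to 3.

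The strand of the counts was the first pattern weighed. A candidate explanation is that reads of a strand-marking kit were counted with the opposite strand setting. It needs the highest features to lie opposite to exons of other genes more often than features in general, and 97% did, against 18.0% of nuclear features. mt-Nd6 also exceeded every other mitochondrial protein gene, with 1002347 reads over the 6 libraries against 58583 for mt-Nd5, the next highest. Recounting the reads with the other setting would test this directly and was not possible from counts.

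Lower counts for heart muscle and energy genes at their own loci were the second pattern. Lower mRNA of these genes was not seen as a shift of the members that could be read. The median log2 fold change of 33 members was 0.0288 in the reading of mRNA. Its interval excludes -0.22, which is 50% of the shift at their own loci. The interval was taken over genes, so it does not measure the spread between libraries and does not exclude lower mRNA. The lists were also picked by their own-locus values in these data, which by itself favours a smaller shift in another reading. Of the sarcomere list 2 members were read as mRNA against 22 at their own loci, and of the respiratory chain 4 against 36. Members without an overlap on the other strand could not be read as mRNA. A candidate explanation is that Acly_KD replicates 1 and 2 hold fewer stray reads of the wrong strand, as their ratio of wrong-strand to mRNA reads was at most 0.917, below the lowest control at 1.06. The genes of this ratio included members of the lower lists, so it is not a separate measure. The stress and fetal list was below all controls in Acly_KD replicate 3 as well (-0.34), where the ratio was highest, so this list stays open. Of the 10 splits of the 6 libraries, the real one among them, 5 gave 11 or more called lists, with 15 as the highest other. By this count the real split did not stand out from mixed groups. Splits that put Acly_KD replicates 1 and 2 with control 1, 2 or 3 gave 12, 14 and 15. In any case 10 splits are too few for a share under 0.05.

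The 6 genes called from the reading of mRNA were the third pattern. Stray reads as a cause were weighed by a fit with the ratio as a term. All 6 genes had 50% or more of their log2 fold change in it, each by more than 1 standard error. The sarcomere median as deposited went from -0.38 to -0.03. Jund still passed in that fit (-0.76, SE 0.15, before and -0.90, SE 0.16, after). The other 5 calls ended, at adjusted p from 0.0604 to 0.135 in edgeR, as values came nearer to zero, errors grew, or both. Ccnd1 went from 0.80 (SE 0.17) to 0.71 (0.18), Mrtfb from 2.00 (0.44) to 1.77 (0.44) and Gm46367 from 1.02 (0.23) to 0.92 (0.26). Cebpb went from -0.84 (0.18) to -0.69 (0.17) and Phkg1 from -1.14 (0.24) to -1.09 (0.26). This fit cannot decide, since the 6 genes were called for a difference between the groups. The ratio followed the groups only weakly (0.569, 0.917 and 1.40 in Acly_KD replicates 1 to 3), so its term could take up little of such a difference. Jund and sarcomere genes such as Ttn were also among the genes of the ratio. Stray reads as a cause stay open. Reads opposite to Xist, which the reading of mRNA gives to Xist, were present in 2 controls alone (129 and 124 reads). On that reading the controls were mixed in Xist RNA, and these 2 differed from all 3 Acly_KD libraries. Reads at genes of the Y chromosome, 2 of them in 1 of these controls, were too few to give the sex of each library. A difference in sex between libraries may therefore add to the calls. With a term for these 2 controls all 6 genes had 50% or more of their log2 fold change, 2 of them by more than 1 standard error. In that fit 0 passed the adjustment, as errors grew with 1 control left to set against the Acly_KD libraries and values came nearer to zero. The values were 0.70 (SE 0.26) for Ccnd1, 1.41 (SE 0.74) for Mrtfb and 0.85 (SE 0.37) for Gm46367. They were -0.43 (SE 0.21) for Jund, -0.76 (SE 0.29) for Cebpb and -0.77 (SE 0.36) for Phkg1. A difference in sex, the knockdown and differences between preparations stay open.

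The real split called 6 genes in the reading of mRNA, 1 of the 10 splits gave as many, and the highest of the others called 2; as deposited the real split called 0, so that 10 of 10 splits gave as many, and the highest other called 1. For the reading of mRNA 10 splits are too few for a share under 0.05. As deposited a real count of 0 is matched by every split, so that comparison could not decide.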
